A study of Homo sapiens with 8 samples.

How the data were processed

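RNA levels were measured on 8 Affymetrix expression arrays of H460, an established human non-small-cell lung cancer cell line. Per the labels, 1 line carried the empty pSuperRetro vector (the vector line) and the other stably expressed an siRNA against DUSP1 and was selected with puromycin (the knockdown line). DUSP1 encodes a nuclear phosphatase that switches off the p38 and JNK kinases. Each line was sampled without treatment (0 h) and after 1, 3 and 6 h with 10 µg/mL cisplatin, a platinum drug that crosslinks DNA. The labels give 1 array for each line and time, no replicate numbers, and no untreated array later than 0 h.

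The deposited table holds 1 intensity per probe set and array. Per the submitters' processing notes the authors used RMA, which corrects background, normalizes between arrays and summarises the probes of a probe set; its version is not given in the sources used here. The deposited intensities are on a linear scale, as the values show: the lowest values per array lay between 5.54 and 5.98, the medians between 25.3 and 27.0, and the highest values between 22000 and 23019. They were turned into log2 values, and no value lay under the floor of 1 set for this step. The number of arrays, 1 per condition, limits the precision of every value. A change shared by most genes cannot be told from a difference in scaling between arrays in these values.

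The table has 54675 probe sets, among them 62 control probe sets. The platform annotation given for them names 1 gene for 41097 probe sets, several genes for 1801 and none for 11777. Of the probe sets with 1 gene, 41043 were matched by Entrez identifier to the RefSeq gene table of assembly GRCh38.p14, used only for names and gene lengths. No coordinates are given, because the probe annotation names no build. Each gene was represented by the single-gene probe set with the highest mean over the 8 arrays. Of 19775 genes, 12252 were tested, those whose highest value reached the median of all values in the table (4.70 on the log2 scale, or 25.9 on the linear scale).

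Line and cisplatin effects were tested with limma (version 3.58.1 in R 4.3.3) in an additive model with exposure time as a factor and line as a term, fitted to all 8 arrays with 3 residual degrees of freedom and empirical Bayes moderation. The line effect is the mean of the 4 differences between the lines at matched times, and each cisplatin effect is the mean change from 0 h over the 2 lines. The model's error term is therefore how much the line difference varies between times. Each SE given with an effect is limma's moderated SE, whose variance is shrunk towards that of all tested genes. It can be smaller or larger than the SE of a gene's own differences. The SD given for DUSP1 is the plain spread of its 4 differences. The arrays serve as each other's replicates across lines or times, not as repeat cultures of a condition, so the p-values measure the spread between these arrays only, and each line is a single selected line. Whether the response differed between the lines was tested as the difference of linear slopes over hours, in a limma model with 4 residual degrees of freedom, since with 1 array per condition a separate interaction at each time leaves no residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05.

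Before the data were examined, 27 gene lists were fixed: MAPK phosphatases, MAPK pathway kinases, AP-1 and ATF/CREB factors, immediate early genes, p53 targets, ATF4 and unfolded protein response genes, NF-kB and cytokine genes, angiogenesis, invasion and extracellular matrix, hypoxia and glycolysis, NRF2 targets, metallothioneins, heat shock genes, nucleotide excision and crosslink repair, apoptosis regulators, S phase and replication, G2 and mitosis, replication-dependent histones, interferon-stimulated genes, TGF-beta, BMP and Notch response, cholesterol biosynthesis, ribosomal proteins, epithelial markers, mesenchymal markers, and markers of fibroblasts, blood cells and neuroendocrine cells. Some lists share members, so their results are not separate evidence. FOS, FOSB, JUN, JUNB and ATF3 belong to both the AP-1 and the immediate early list. ATF3 and ATF5 belong to the AP-1 and ATF4 lists, and BTG2 and PLK2 to the immediate early and p53 lists. Each list was tested in each of 5 comparisons with limma's camera at a preset correlation between genes of 0.01, which compares the list with all other tested genes, with adjustment over the 27 lists of a comparison. Camera with the correlation estimated from these arrays, and fry, were alternatives. With an estimated correlation camera tests on the residual degrees of freedom of the fit (3 or 4), which raises p-values whatever the correlation. In simulated genes that vary independently, a shifted list had camera p = 2.95e-34 with the preset correlation and 0.000908 with an estimated one (line effect). A call lost with an estimated correlation therefore does not show that the genes vary together.

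The genes named were chosen by a rule that was also fixed before the data were examined. DUSP1 came first with all its probe sets. For the line effect these were the 12 genes with the largest mean difference in each direction among those past the threshold and of the same sign at all 4 times. For cisplatin they were the 12 largest changes in each direction at 6 h and the 6 largest at 3 h and at 1 h, among genes past the threshold and of the same sign in both lines. For the response difference, where no gene passed, they were the 8 genes in each direction with the largest mean of the differences of change at 3 and 6 h, with no test. Up to 4 members of each list were added per comparison, those past the threshold first. Of the 88 results this rule gave by size, 39 had another probe set of the same gene past the filter, and in 3 of these another probe set changed in the opposite direction (TANC1 at 6 h, TBC1D31 and IDI1 at 3 h).

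Alternatives were other filters on dim genes, quantile normalization or median centring of the deposited values, the mean of a gene's probe sets, probe sets in place of genes, another variance prior, other model terms and time scales, other list tests, and leaving out each pair of arrays of a time. The changes at 3 and 6 h against 1 h, the list tests without the 0 h arrays, and fits without each single array were added after the data had been seen. The list tests without the 0 h arrays used camera with the preset correlation only, and no correlation was estimated for them. The fits were tested on simulated data for the 12252 genes, with 50 changed genes at each of several sizes. For a change of 1 on the log2 scale, the share recovered was 100% for the line effect, 98% for the 6 h effect, and 34% for a response difference that reaches this size at 6 h. For a response difference of 2 it was 98%. Unchanged genes called numbered 19 for the line effect, 14 for the 6 h effect and 10 for the response difference. The simulated values held no change over time common to the lines, and their noise was scaled to the additive fit. In the arrays, uneven changes over time add to the error of the slope fit, so the shares for response differences are too high. Probe sets with several genes or none were left out of the gene tests. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. The genes shown as time courses for the response difference were chosen after the values were seen.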

Results

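The arrays followed the response of H460 lung cancer cells to cisplatin over 6 h in a line with an empty vector and in a line with DUSP1 knocked down, to find which drug responses depend on DUSP1. Values are log2 intensities from 8 arrays, 1 for each line at 0, 1, 3 and 6 h, and there were no replicate cultures. The 3 prime to 5 prime difference of the GAPDH control probe sets, a sign of RNA quality, lay between 0.14 and 0.24 on all arrays, and that of the beta-actin sets between 0.12 and 0.45. Both were highest on the knockdown 1 h array, and the next highest values were 0.19 and 0.30 on the vector 6 h array. The first principal component, with 47.0% of the variance, set the 6 h arrays of both lines apart from the rest. The 0 h arrays also stood apart: 263 genes differed at least 2-fold between 0 and 1 h in the vector line and 336 in the knockdown line. Between 1 and 3 h these numbers were 30 and 42, and between 3 and 6 h 631 and 723.

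DUSP1 was measured first, because its level checks the labels. Its brightest probe set read 12.07, 8.86, 10.79 and 11.83 at 0, 1, 3 and 6 h in the vector line and 10.32, 8.49, 9.07 and 10.68 in the knockdown line. DUSP1 was thus lower in the knockdown line at each of the 4 times, by a mean of -1.25 ± 0.65 (SD, n = 4 times; limma adjusted p = 0.0171). The differences were -1.75, -0.37, -1.72 and -1.15 from 0 to 6 h. A dimmer probe set had a mean difference of -0.88 and was 0.20 higher in the knockdown line at 1 h (adjusted p = 0.117, limma over probe sets). The dimmest had a mean difference of -0.13 (adjusted p = 0.600). Without the 3 h arrays the mean difference of DUSP1 was -1.09, with a limma adjusted p of 0.118, and without the 6 h arrays it was -1.28, with an adjusted p of 0.0560. The difference also did not pass limma with a trended, robust variance prior (adjusted p = 0.0664), no time term (0.701) or hours as a number (0.463).

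**Figure D1:**
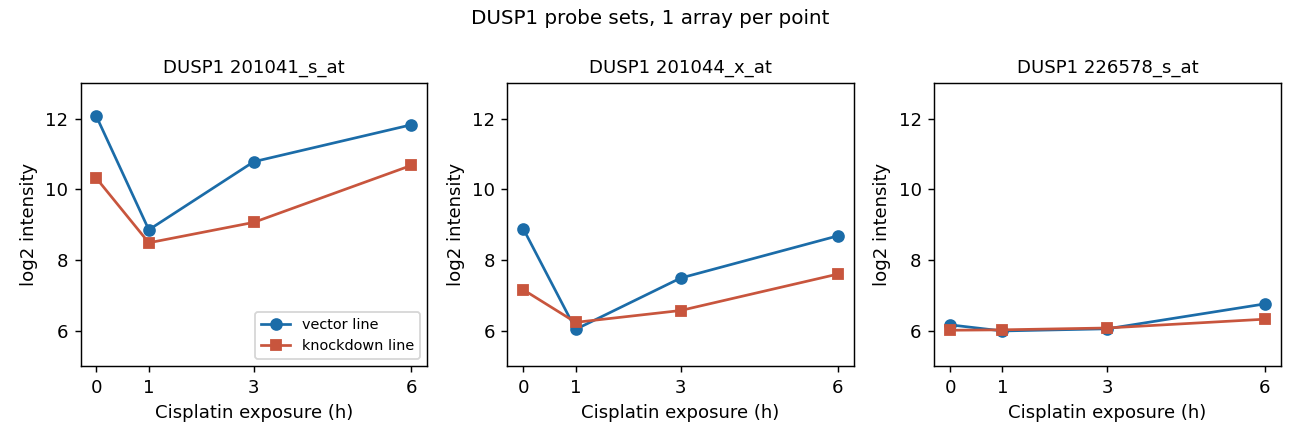
log2 intensity of the 3 DUSP1 probe sets (y axis) against hours of cisplatin exposure (x axis), 1 array per point, with the vector line as circles and the knockdown line as squares. The brightest probe set lies lower in the knockdown line at all 4 times, with the smallest gap (-0.37) at 1 h.

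The comparison of the lines over all times asked what distinguishes cells with the DUSP1 siRNA from vector cells. COL12A1, a fibril-associated collagen, was 3.61 ± 0.15 (moderated SE, n = 4 times) higher in the knockdown line (adjusted p = 3.52e-05, limma). ROBO1, a SLIT receptor, was 3.31 ± 0.23 higher (adjusted p = 0.000410). SERPINB11, a serpin, was lower by -4.79 ± 0.12 (adjusted p = 2.26e-06), and LUM, the matrix proteoglycan lumican, by -4.40 ± 0.17 (adjusted p = 2.87e-05). MMP1, the interstitial collagenase, had a mean difference of -5.05 ± 0.91 (adjusted p = 0.0197), but not at all times alike: it read 9.58 in the knockdown line at 0 h and 3.31, 3.30 and 3.26 at 1, 3 and 6 h, against 10.29, 9.65, 9.76 and 9.94 in the vector line.

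Among 12252 tested genes, 1000 differed between the lines at a limma adjusted p under 0.05, 386 higher and 614 lower in the knockdown line, and 994 of them kept their sign at all 4 times. At least 2-fold differences numbered 53 higher and 101 lower. Other genes higher in the knockdown line were the succinate receptor SUCNR1 (3.02), the Wnt ligand WNT5A (2.61), the lipoxygenase ALOX15 (2.41) and MAL2 (2.37). Further ones were the carbonic anhydrase CA2 (2.29), the fibrinogen chain FGG (2.13), the spermine oxidase SMOX (2.08), the complement receptor C5AR1 (2.04), MICAL2 (1.99) and the microtubule-associated protein gene MAP2 (1.88). Their adjusted p-values lay between 1.28e-05 for SUCNR1 and 0.0270 for FGG. Lower genes were the lipoprotein-associated phospholipase PLA2G7 (-3.60), the adaptor SH2D2A (-3.33), CLTRN (-2.87) and the peroxidasin PXDN (-2.87). So were the interleukin 13 decoy receptor IL13RA2 (-2.66), the lipid kinase PIP5K1B (-2.57), the amino acid transporter SLC38A5 (-2.55), the serpin SERPIND1 (-2.48) and NAV2 (-2.43). Their adjusted p-values lay between 2.26e-06 for SH2D2A and 0.0228 for SLC38A5. COL12A1, MAL2 and FGG in the vector line, and MMP1, LUM, CLTRN, IL13RA2, PIP5K1B, SLC38A5 and NAV2 in the knockdown line, read under the limit for dim genes of 4.70 at 3 or 4 of the 4 times. SERPIND1 in the knockdown line and MAP2 in the vector line did so at 2 times. PXDN in the knockdown line and CA2 and MICAL2 in the vector line did so at 1. Differences measured against values this dim are not exact sizes.

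**Figure D2:**
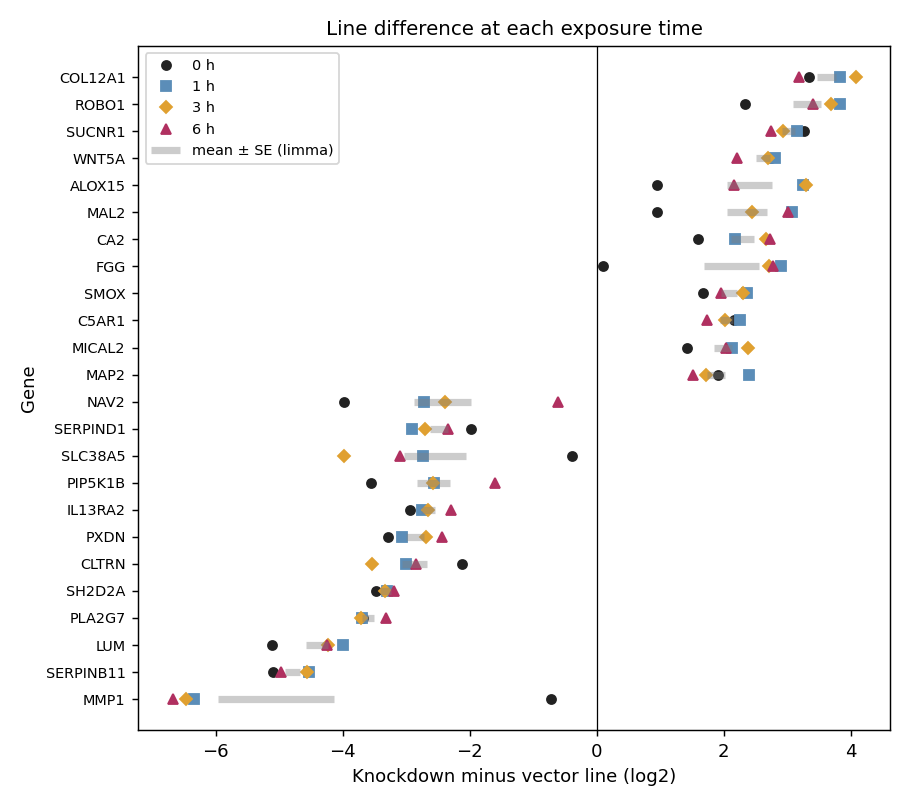
Knockdown minus vector line (x axis, log2) for the 24 genes with the largest line differences (y axis), with 1 symbol per exposure time and a grey bar for the limma mean ± SE. MMP1 at 0 h, FGG at 0 h and SLC38A5 at 0 h lie far from the other times, while SH2D2A and PLA2G7 barely move.

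Of the fixed lists, 3 stood apart in the line comparison by camera, and without the 0 h arrays these 3 and 2 more, the cholesterol genes (median -0.24, adjusted p = 0.00132) and the metallothioneins (-0.25, 0.0383). Calls without the 0 h arrays used the preset correlation only. With all arrays neither passed camera with the preset correlation (adjusted p = 0.582 for the cholesterol genes and 0.840 for the metallothioneins). With an estimated correlation the values were 0.855 and 0.961. Those values do not test the calls without the 0 h arrays. Interferon-stimulated genes were lower as a group: 1 of 19 measured members was higher, 6 were lower and 12 did not pass (1 higher and 10 lower when adjusted over the list alone; camera adjusted p = 0.0133, but adjusted p = 0.824 with an estimated correlation). Examples were GBP1 (-1.02), the RNA sensor IFIH1 (-0.82) and OAS1 (-0.71), while IFI44L was 0.89 higher. Of the invasion and extracellular matrix genes, 2 of 19 were higher, 6 lower and 11 did not pass (2 and 8 adjusted over the list alone; camera adjusted p = 0.0428, adjusted p = 0.824 with an estimated correlation). Besides MMP1 these included the plasminogen activators PLAT (-2.06) and PLAU (-1.30) and the protease inhibitor TIMP2 (-1.83). Of 29 p53 targets, 2 were higher, none lower and 27 did not pass (3 higher adjusted over the list alone; camera adjusted p = 0.0260, adjusted p = 0.824 with an estimated correlation), namely SESN1 (0.61) and PMAIP1 (0.54).

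The MAPK and AP-1 lists did not stand apart between the lines. Of 11 MAPK phosphatases, 2 were lower, DUSP1 and the ERK phosphatase DUSP6 (-0.94), and 9 did not pass (3 lower adjusted over the list alone; camera adjusted p = 0.603). None of 16 MAPK pathway kinases passed, also none adjusted over the list alone (camera adjusted p = 0.192). Of 22 AP-1 and ATF/CREB factors, 2 were higher and 2 lower, among them FOS (-0.95) and ATF5 (0.79), with 2 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.840). Of 26 immediate early genes, 1 was higher (TRIB1, 1.04) and 6 lower, including CCN2 (-1.19) and KLF2 (-0.72), with 1 and 8 adjusted over the list alone (camera adjusted p = 0.0674). Among single members of other lists, ZEB1, a repressor of epithelial genes, was 1.24 higher, FGF2 1.24 higher and PTGS2 1.56 higher. KRT19 (-0.76), VEGFC (-1.16), BMP2 (-1.72) and TGFB1 (-0.95) were lower. Markers of other cell types moved singly: of 6 fibroblast markers LUM was lower and COL1A1 0.54 higher, of 9 blood cell markers SRGN was lower (-0.46), and of 7 neuroendocrine markers ENO2 was lower (-0.73). The line differences at 0 h correlated with the mean of the later times across genes at r = 0.50 (genes are not independent replicates), against 0.74 between 1 and 3 h, 0.58 between 1 and 6 h and 0.62 between 3 and 6 h.

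The number of genes in the line comparison rested on the pairs of arrays used: it was 159 without the 3 h arrays, 278 without the 1 h arrays, 521 without the 6 h arrays and 1127 without the 0 h arrays. It was 68 with no term for time and 252 with hours as a number. Each line is 1 selected line, so an effect of the siRNA cannot be told from an effect of selection, and there were no untreated arrays at 1, 3 or 6 h.

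The cisplatin comparisons asked how both lines changed from 0 h. At 6 h, targets of p53 rose and genes of mitosis fell as groups by camera, though neither list passed with an estimated correlation (adjusted p = 0.0845 for both). Both passed fry (adjusted p = 0.000752 for both). The estimated correlations, 0.0032 for the p53 targets and 0.0156 for the mitosis genes, lay near the preset 0.01. The loss of both calls thus came mainly with the fewer degrees of freedom. EGR1, an early growth response factor, rose by 4.07 ± 0.65 (SE, n = 2 lines; adjusted p = 0.00310, limma) and JUN, a subunit of AP-1, by 3.80 ± 0.25 (adjusted p = 0.000157). CDKN1A, which encodes the cell cycle inhibitor p21, rose by 2.90 ± 0.15 (adjusted p = 8.98e-05) and the proapoptotic PMAIP1 by 2.40 ± 0.16 (adjusted p = 0.000153). TANC1 fell by 3.93 ± 0.49 (adjusted p = 0.00117), with another of its probe sets moving the other way, and the ephrin receptor EPHA4 fell by 3.65 ± 0.19 (adjusted p = 9.23e-05). In total 4526 genes changed at a limma adjusted p under 0.05, 1879 higher and 2647 lower, with 175 at least 2-fold higher and 806 at least 2-fold lower.

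The other large increases at 6 h were SERTAD1 (3.31), FOS (3.05), the stress factor ATF3 (2.88), and the chemokine CXCL3 (2.75). They also included the growth factor HBEGF (2.74), the TRAIL decoy receptor TNFRSF10D (2.57), NFKBIZ (2.40) and adrenomedullin, ADM (2.37). The other large decreases were the Wnt pathway factor TCF7L2 (-3.31), the chromatin gene ARID4B (-3.24), the cadherin CDH10 (-3.16) and EEIG2 (-3.10). ANKRD44 (-3.06), PAG1 (-3.03), the tensin TNS3 (-3.01), ZNF804A (-2.88), the phosphodiesterase PDE7B (-2.87) and NAP1L3 (-2.84) fell as well. All of these had a limma adjusted p under that of EGR1 except CXCL3 (0.0204), NAP1L3 (0.00808) and NFKBIZ (0.00427). EPHA4, ANKRD44 and ZNF804A read under 4.70 at 6 h in both lines, as did TANC1, TCF7L2, ARID4B and NAP1L3 in 1 line, and TNFRSF10D did so at 0 h in both lines and FOS in 1. The sizes of these changes are not exact.

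Of 29 p53 targets, 21 rose, none fell and 8 did not pass at 6 h (25 rose when adjusted over the list alone; camera adjusted p = 4.15e-12, adjusted p = 0.0845 with an estimated correlation). They included SERTAD1, CDKN1A, PMAIP1 and the secreted factor GDF15 (2.36). Of 29 G2 and mitosis genes, 26 fell, none rose and 3 did not pass (26 adjusted over the list alone; camera adjusted p = 4.15e-12, adjusted p = 0.0845 with an estimated correlation), such as GTSE1 (-1.79) and the kinesins KIF20A (-1.71) and KIF11 (-1.55). Of 26 immediate early genes, 18 rose and 3 fell (the same numbers adjusted over the list alone; camera adjusted p = 1.12e-05, adjusted p = 0.609 with an estimated correlation). Of 22 AP-1 and ATF/CREB factors, 9 rose and 4 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.0298, adjusted p = 0.609 with an estimated correlation), with JDP2, a repressor of AP-1, at -2.79. In 6 h against 1 h the AP-1 list did not pass (adjusted p = 0.0943), while the p53 (7.28e-11), G2 and mitosis (1.23e-12) and immediate early lists (1.87e-07) did. Of 16 cholesterol biosynthesis genes, 14 fell and 2 did not pass (16 fell adjusted over the list alone; camera adjusted p = 6.60e-06, adjusted p = 0.661 with an estimated correlation), led by LSS (-2.06), HMGCS1 (-1.60) and DHCR7 (-1.58). In 6 h against 1 h, which leaves out the 0 h arrays, the median of the cholesterol list was 0.33, with 7 genes higher and 1 lower, and its lower level at 6 h was thus seen against the 0 h arrays only.

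**Figure D3:**
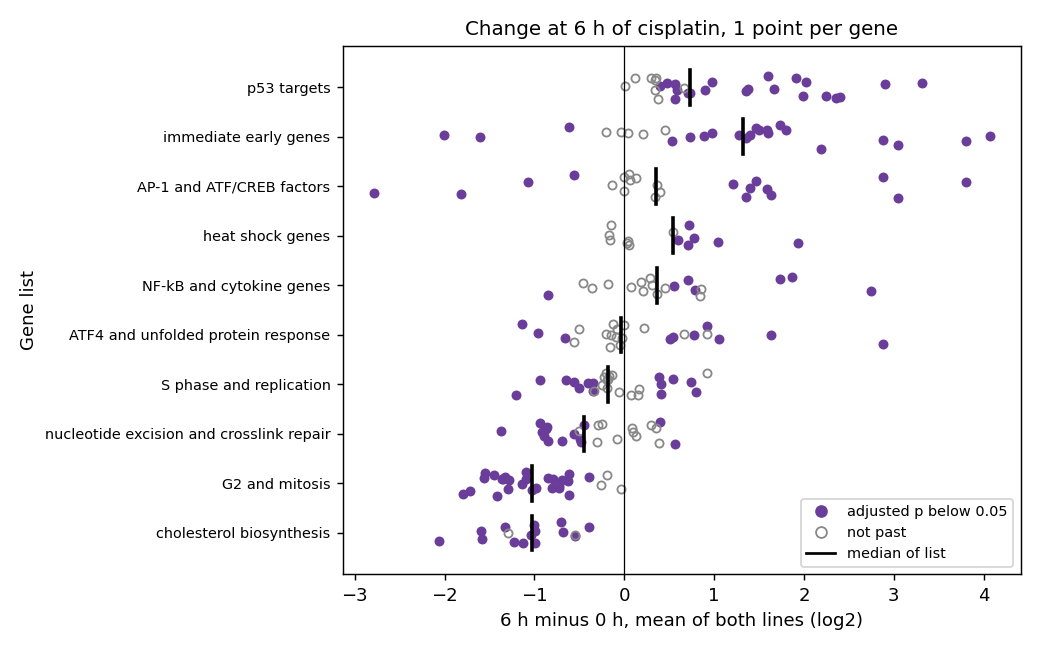
Change from 0 h to 6 h of cisplatin, mean of both lines (x axis, log2), for the genes of 10 fixed lists (y axis), 1 point per gene, filled where the limma adjusted p is under 0.05, with the list median as a black bar. The p53 targets lie to the right of 0 with a median of 0.73 and the G2 and mitosis genes to the left with a median of -1.03.

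The remaining lists did not pass camera at 6 h, and their counts follow as rose and fell, then adjusted over the list alone. For 11 MAPK phosphatases they were 5 and 1 (5 and 1), with DUSP2 at 2.13, DUSP5 at 1.17 and DUSP7 at 1.01. For 16 MAPK pathway kinases they were 0 and 6 (0 and 6), with MAP3K5 at -1.61 and MAPK8 at -0.68. For 24 ATF4 and unfolded protein response genes they were 7 and 3 (7 and 3), with ATF5 at 1.63. For 19 NF-kB and cytokine genes they were 6 and 1 (6 and 1), with CXCL2 at 1.87 and CCL20 at 1.74. For 18 angiogenesis genes they were 3 and 5 (4 and 5), with NRP1 at -2.27. They were 2 and 4 (2 and 4) for 19 invasion and extracellular matrix genes, and for 20 hypoxia and glycolysis genes 2 and 3 (2 and 2). For 22 NRF2 targets they were 4 and 4 (4 and 4), with HMOX1 at 1.55. The 7 metallothioneins had 1 and 0 (1 and 0), namely MT1X at 1.18, and the 13 heat shock genes 6 and 0 (6 and 0), with HSPA6 at 1.93 and DNAJB1 at 1.04. For 25 nucleotide excision and crosslink repair genes they were 2 and 12 (3 and 13), with FANCI at -1.37 and REV1 at -0.94. The 25 apoptosis regulators had 5 and 6 (5 and 7), with FAS at 1.36 and BCL2 at -1.80. The 28 S phase and replication genes had 6 and 8 (6 and 8).

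For 8 replication-dependent histones the counts were 1 and 0 (1 and 0), for 19 interferon-stimulated genes 1 and 7 (2 and 7), with RIGI at -1.33. The 19 TGF-beta, BMP and Notch response genes had 6 and 4 (7 and 4), with TGFB2 at -1.99 and NRARP at 1.60. For 22 ribosomal proteins they were 1 and 0 (1 and 0), for 13 epithelial markers 2 and 4 (2 and 5), with JUP at -1.08. The 10 mesenchymal markers had 4 and 4 (4 and 4), with ZEB1 at -1.65 and SNAI2 at 1.42. For 6 fibroblast markers they were 0 and 0 (0 and 0), for 9 blood cell markers 3 and 1 (3 and 1), and for 7 neuroendocrine markers 0 and 1 (0 and 0). The camera adjusted p-values of these lists lay between 0.0645 for the repair genes and 0.970 for hypoxia and glycolysis. In 6 h against 1 h, without the 0 h arrays, 6 of them passed by camera. Upward these were the MAPK phosphatases (median 0.82, adjusted p = 2.09e-05), NF-kB genes (0.55, 0.000584), heat shock genes (0.43, 0.000769), histones (0.40, 0.0170) and metallothioneins (0.27, 0.0357), and downward the repair genes (-0.25, 0.0357). The calls used the preset correlation only. Against 0 h, with all arrays, these lists had not passed camera with the preset correlation, nor did they with an estimated one (adjusted p = 0.609 to 0.864). Those values concern another comparison and do not test the calls against 1 h. The medians of 7 of the 27 lists, the interferon-stimulated genes among them (-0.22 as deposited, 0.03 after quantile normalization), changed sign between scalings at 6 h.

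After quantile normalization of the table, the split at 6 h was 2748 higher and 2092 lower, against 1879 and 2647 as deposited, and the median change of all tested genes was 0.10 in place of 0.01. At 1 h the split was 398 and 430, and at 3 h 290 and 358. The number of genes was 2537 without the vector 6 h array, 2997 without the knockdown 6 h array and 3057 in 6 h against 1 h without the 0 h arrays, of which 2243 were among the 4526.

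At 1 h, genes of cholesterol synthesis fell most, though their list did not pass camera with an estimated correlation (adjusted p = 0.657). HMGCS1, the enzyme that makes HMG-CoA, fell by 3.62 ± 0.35 (SE, n = 2 lines; adjusted p = 0.00829, limma), INSIG1, a sterol-regulated brake on SREBP, by 3.34 ± 0.47 (adjusted p = 0.0137) and the methylsterol oxidase MSMO1 by 2.55 ± 0.32 (adjusted p = 0.0110). The cytokine IL6 fell by 2.59. DUSP1 itself fell by 2.52 ± 0.31 (adjusted p = 0.0101), and the phosphatidate phosphatase LPIN1 fell by 2.35. The pentraxin PTX3 rose by 1.77 ± 0.29 (adjusted p = 0.0200), ZBTB24 by 1.69 (from under 4.70 at 0 h in the vector line), C5AR1 by 1.54, the netrin receptor UNC5B by 1.53, TUBE1 by 1.29 and TMA16 by 1.24. Altogether 826 genes changed, 267 higher and 559 lower.

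Of 16 cholesterol biosynthesis genes, 13 fell at 1 h, none rose and 3 did not pass (15 fell and 1 rose when adjusted over the list alone; camera adjusted p = 1.36e-12, adjusted p = 0.657 with an estimated correlation). Of 19 interferon-stimulated genes 6 fell, including IRF9 (-1.08), also 6 adjusted over the list alone (camera adjusted p = 0.000742). Of 24 ATF4 and unfolded protein response genes 4 rose, including the asparagine synthetase ASNS (1.01) and CEBPG (0.98), with 6 up and 1 down adjusted over the list alone (camera adjusted p = 0.00229). Of 29 p53 targets 3 rose, PHLDA3 (0.78), TNFRSF10B (0.68) and TIGAR (0.51), with 12 up and 3 down adjusted over the list alone (camera adjusted p = 0.00967). Of 28 S phase genes MCM4 fell (-0.67), with 7 down adjusted over the list alone (camera adjusted p = 0.00967). Of 8 histones 3 fell, with 5 adjusted over the list alone (camera adjusted p = 0.0298). Of 13 heat shock genes DNAJB4 fell (-0.78) and CHORDC1 rose (0.72), with 1 up and 4 down adjusted over the list alone (camera adjusted p = 0.0426). For all of these, adjusted p = 0.657 with an estimated correlation. Of 11 MAPK phosphatases DUSP1, DUSP10 (-1.53) and DUSP4 (-0.88) fell, with 1 up and 5 down adjusted over the list alone (camera adjusted p = 0.198). The 1 h count was 34 without the vector 1 h array, 10 without the knockdown 1 h array and 168 without the 3 h arrays.

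At 3 h the transcription factor EGR1 rose by 3.48 ± 0.65 (SE, n = 2 lines; adjusted p = 0.0301, limma), FOS by 1.92 ± 0.25 (adjusted p = 0.0124) and FOSL1 by 1.24 ± 0.15 (adjusted p = 0.0118). PTX3 rose by 1.34, C5AR1 by 1.32 and TBC1D31 by 1.20, the last with another probe set moving the other way. FOS and TBC1D31 each read under 4.70 in 1 line at 0 h, so the sizes of their changes are not exact. DUSP6 fell by 2.36 ± 0.25 (adjusted p = 0.0103), and HMGCS1 (-2.44), MSMO1 (-2.39), INSIG1 (-2.23), LPIN1 (-2.21) and IDI1 (-2.11) were below their 0 h level. In all 765 genes changed, 224 higher and 541 lower. In 3 h against 1 h, which leaves out the 0 h arrays, 3 genes changed, and HMGCS1 was 1.19 higher at 3 h (adjusted p = 0.0384, limma).

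Of 22 AP-1 and ATF/CREB factors 4 rose at 3 h and none fell (5 up and 2 down adjusted over the list alone; camera adjusted p = 0.00305, adjusted p = 0.691 with an estimated correlation). Of 26 immediate early genes 5 rose and 4 fell (5 up and 6 down adjusted over the list alone; camera adjusted p = 0.673). Of 16 cholesterol genes 13 fell (15 down and 1 up adjusted over the list alone; camera adjusted p = 1.55e-11, adjusted p = 0.691 with an estimated correlation). Of 19 interferon-stimulated genes 6 fell (6 adjusted over the list alone; camera adjusted p = 0.00184, adjusted p = 0.691 with an estimated correlation). Of 29 p53 targets 4 rose, including CDKN1A (0.98), and TP53I3 fell (-0.59), with 11 up and 1 down adjusted over the list alone (camera adjusted p = 0.00580, adjusted p = 0.691 with an estimated correlation). Of 24 ATF4 genes 3 rose, with 7 adjusted over the list alone (camera adjusted p = 0.0148, adjusted p = 0.752 with an estimated correlation). Of 8 histones 3 fell, with 5 adjusted over the list alone (camera adjusted p = 0.0448, adjusted p = 0.691 with an estimated correlation). In 3 h against 1 h, without the 0 h arrays, the p53 targets did not pass (median -0.01, adjusted p = 0.915), nor did the ATF4 (0.329), interferon-stimulated (0.915) or histone lists (0.915). The AP-1 factors passed upward (0.0427), but with a median of -0.0023 and 0 of 22 members past the threshold. The cholesterol genes (0.00137) passed upward, with 1 of 16 members past the threshold. So did the S phase (1.18e-07), heat shock (0.00849) and NRF2 lists (0.0427), with 0 of 28, 0 of 13 and 0 of 22 members past it. These calls used the preset correlation only. The 3 h count was 0 without the vector 3 h array (2055 genes at an unadjusted limma p under 0.05), 0 without the knockdown 3 h array (1503 at unadjusted p) and 311 without the 1 h arrays.

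The central question of the design was which cisplatin responses differ between the lines. As groups, NF-kB and cytokine genes, ATF4 and unfolded protein response genes and metallothioneins had lower slopes over the 6 h in the knockdown line, and heat shock genes had higher slopes. These group results by camera did not hold with an estimated correlation (adjusted p = 0.461 for each of the 3 lower lists and 0.717 for heat shock genes), and the metallothioneins did not pass without the 0 h arrays (0.103). The chemokine CXCL3 read 6.36, 5.89, 8.47 and 10.78 from 0 to 6 h in the vector line and 8.36, 7.66, 8.43 and 9.44 in the knockdown line. CCL20, another chemokine, read 6.12 at 0 h and 9.41 at 6 h in the vector line and 8.09 and 8.28 in the knockdown line. The stress factor DDIT3 went from 8.43 to 10.54 in the vector line and from 9.79 to 9.53 in the knockdown line. The chaperone DNAJB1 went from 8.97 to 9.58 in the vector line and from 8.64 to 10.10 in the knockdown line. No single gene passed the test of the slope difference (0 of 12252 by limma, 253 at an unadjusted p under 0.05, where chance gives 612.6). Also 0 genes passed for the slope of either line alone (2734 genes in the vector line and 2497 in the knockdown line at an unadjusted p under 0.05). These tests assume a straight line over hours, and changes that were uneven over time add to their error. A count of 0 therefore does not show that the lines responded alike.

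**Figure D4:**
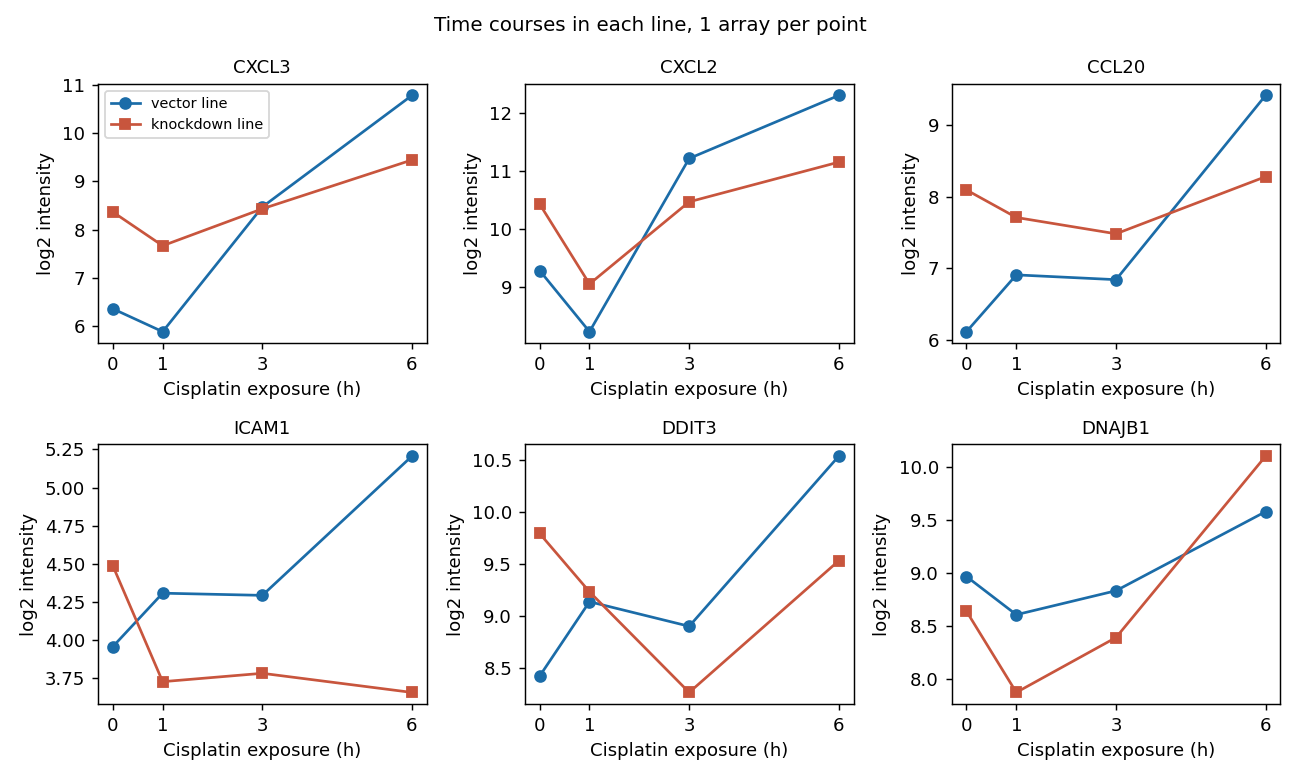
log2 intensity (y axis) against hours of cisplatin exposure (x axis) for CXCL3, CXCL2, CCL20, ICAM1, DDIT3 and DNAJB1, 1 array per point, with the vector line as circles and the knockdown line as squares; the y axes differ. The 3 chemokines start higher in the knockdown line and end higher in the vector line, as CXCL3 does with 10.78 against 9.44 at 6 h.

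Of 19 NF-kB and cytokine genes, 17 had a lower slope in the knockdown line (median difference -0.11 per hour), none passed over all genes and 3 passed when adjusted over the list alone (camera adjusted p = 1.95e-07, adjusted p = 0.461 with an estimated correlation). Their slope differences included CXCL3 (-0.59), CCL20 (-0.47), CXCL2 (-0.40) and ICAM1 (-0.29). Of 24 ATF4 and unfolded protein response genes, 20 had a lower slope (median -0.11; none passed, also none adjusted over the list alone; camera adjusted p = 3.92e-07, adjusted p = 0.461 with an estimated correlation), among them DDIT3 (-0.35) and CHAC1 (-0.34). All 7 metallothioneins had a lower slope (median -0.14; none adjusted over the list alone; camera adjusted p = 3.43e-07, adjusted p = 0.461 with an estimated correlation), with MT2A at -0.23. Of 13 heat shock genes, 12 had a higher slope (median 0.09; none adjusted over the list alone; camera adjusted p = 0.00466, adjusted p = 0.717 with an estimated correlation), with HSPA6 at 0.18 and DNAJB1 at 0.17. Of 28 S phase genes, 23 had a higher slope (median 0.03; none adjusted over the list alone; camera adjusted p = 0.010, adjusted p = 0.842 with an estimated correlation), with the cyclin CCNE2 at 0.36. These directions were the same after quantile normalization and median centring.

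Neither the MAPK phosphatases (median slope difference -0.02; camera adjusted p = 0.388) nor the MAPK pathway kinases (0.00; adjusted p = 0.773) stood apart in this comparison. The AP-1 and ATF/CREB factors had a median of -0.04 (adjusted p = 0.0936) and the p53 targets of -0.02 (adjusted p = 0.337). The largest untested differences of change, as means of 3 and 6 h, were NCAM1 (3.23), CYTIP (2.89), NRN1 (2.64), FGG (2.64), NAV2 (2.48), LPL (2.32), LINC03125 (2.16) and NDN (2.12), which changed more upward in the knockdown line. In the other direction they were MMP1 (-5.85), S100A3 (-3.16), SLC38A5 (-3.14), CXCL3 (-2.69), IGFBP7 (-2.69), ADGRG1 (-2.47), NAP1L3 (-2.31) and CCL20 (-2.22). CYTIP read under 4.70 in the knockdown line at all times and in the vector line at 1, 3 and 6 h, so its value rests on the vector 0 h array alone. LINC03125, NAV2, MMP1 and SLC38A5 read under 4.70 in the knockdown line at 3 of the 4 times, NCAM1 and NAP1L3 at 2 and S100A3 at 1, as FGG did in the vector line at 3 and NRN1 at 1. Their sizes are not exact. Most of these differences were already there at 1 h: IGFBP7 had a change of 0.11 in the vector line and -2.48 in the knockdown line by then. All of them subtract 1 untreated array per line. MMP1 in the knockdown line, for example, read 9.58 at 0 h against a mean of 3.29 at 1, 3 and 6 h. A peculiarity of a 0 h array therefore cannot be told from a difference in the response to cisplatin. Without the 0 h arrays the list test by camera gave lower slopes for the NF-kB and cytokine genes (adjusted p = 8.80e-09) and the ATF4 genes (9.49e-06), and higher slopes for the heat shock (2.71e-06) and S phase genes (0.0223). It then also gave lower slopes in the knockdown line for the immediate early genes (median -0.10, adjusted p = 0.000245, against 0.0936 with all arrays) and the AP-1 and ATF/CREB factors (-0.06, 0.0377). In both lists 0 members passed, and these calls used the preset correlation only. With all arrays neither list passed with the preset correlation. With an estimated one, camera gave an adjusted p of 0.862 for the immediate early genes and 0.461 for the AP-1 factors. Those values do not test the calls without the 0 h arrays.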

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

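The tests of the 0 h arrays and the NF-kB and other list tests without the 0 h arrays were chosen only after the result was seen, while camera with an estimated correlation was planned but taken as a test of the NF-kB result afterwards, and the limits of the tests on shared RNA and on a shared response of the first hour were set, the latter more than once, after their values were known.

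The arrays without treatment stood apart from those at 1 and 3 h in both lines, and every change from 0 h rests on them. If RNA of the other line had been mixed into these arrays, genes specific to 1 line would all show a like share of the other line's level, but 60% of 20 such genes lay under a share of 0.1, so a uniform mixture is unlikely. This test was at first made on the knockdown array alone, where 63.6% of 11 genes lay under 0.1 while the other 4, SLC38A5 (0.904), MMP1 (0.864), TIMP2 (0.634) and SERPIND1 (0.402), had high shares that stay unexplained. Swapped labels would give a negative correlation of the line difference at 0 h with the mean of later times, and it was r = 0.502. Whether a response to the drug in the first hour, shared by both lines, could be the cause stays open, since there is no untreated array at 1 h: of the genes that changed 2-fold from 0 to 1 h in the knockdown line, 24.1% changed likewise in the vector line, against 26.2% from 1 to 3 h and 57.5% from 3 to 6 h. Of all 12252 tested genes, 263 changed 2-fold in the vector line from 0 to 1 h, so the 24.1% lies above that base rate. Across genes the changes of the lines correlated at r = 0.503 from 0 to 1 h, 0.248 from 1 to 3 h and 0.798 from 3 to 6 h.

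Groups of genes whose response over time differed between the lines were picked out because camera called them. These were the NF-kB and cytokine genes (median slope difference -0.113 per hour), the ATF4 and unfolded protein response genes (-0.107), the metallothioneins (-0.141), the heat shock genes (0.0904) and the S phase genes (0.0323). For the NF-kB genes the 0 h arrays alone do not account for the call, since without them the median was -0.170 and camera with the preset correlation still called the list. A higher starting level in the knockdown line is not excluded this way, since CXCL3 was higher there at 1 h too. Whether genes that vary together could produce the call cannot be settled with these arrays. With the correlation estimated from them (0.188 for this list) the camera adjusted p was 0.461, but that option also tests on the few residual degrees of freedom. The lost call therefore does not measure how far these genes vary together. A repeat of both lines at 0 and 6 h with 3 cultures each would test the call. Of the other lists, the ATF4 (adjusted p = 9.49e-06), heat shock (2.71e-06) and S phase genes (0.0223) were still called without the 0 h arrays, and the metallothioneins were not (0.103); none of the 4 was called with an estimated correlation (0.461, 0.717, 0.842 and 0.461).

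Among the genes with the largest untested differences of change, some were picked out because their changes had opposite signs in the lines. This held at each of 1, 3 and 6 h, whatever the size of the change. They were NCAM1 (3.23), NRN1 (2.64), FGG (2.64), LINC03125 (2.16), NDN (2.12) and IGFBP7 (-2.69), given as the mean of the differences at 3 and 6 h. Their causes were not tested. All changes of a line subtract the same 0 h array, so agreement over the times is not repeated evidence. At 6 h, 1585 of 4926 probe sets without a single gene name also passed the threshold, 836 higher and 749 lower, and these were not analysed here.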

How the results depend on the processing

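The fits that leave out single arrays, the changes at 3 and 6 h taken against 1 h, and the list tests without the 0 h arrays were chosen only after the data were seen. All other alternatives, leaving out each pair of a time among them, were fixed before. Testing probe sets in place of genes gave 1664 for the line effect and 1685, 1285 and 10991 at 1, 3 and 6 h, as more units were tested. A trended, robust variance prior gave 1310 genes at 1 h and 1189 at 3 h. For the line effect, no time term gave 68 genes and hours as a number 252, and leaving out pairs gave 159 to 1127. Leaving out a pair or an array gave 10 to 694 genes at 1 h, 0 to 644 at 3 h and 2537 to 4103 at 6 h. At 6 h, no line term gave 2929 genes, and the mean of 1, 3 and 6 h against 0 h gave 514. The response difference stayed at 0 genes except with the treated times against 0 h, which gave 3. The DUSP1 difference was -1.25 but no longer passed with the trended, robust prior (adjusted p = 0.0664), no time term (0.701) or hours as a number (0.463), and it was -1.54 to -1.08 with pairs left out (0.00529 to 0.118) and -0.75 with the mean of its probe sets (0.0364). Of 135 list tests 26 passed by camera with the preset correlation, 20 by fry (7 of them shared) and 0 by camera with an estimated correlation. In 3 h against 1 h, without the 0 h arrays, 3 genes passed, and these genes turned sign: PTX3 (-0.43), C5AR1 (-0.21), HMGCS1 (1.19), MSMO1 (0.16), INSIG1 (1.11), LPIN1 (0.13) and IDI1 (0.23). The direction given by camera turned likewise at 3 h for ATF4 genes (-0.0761), cholesterol genes (0.14), histones (median -0.0179) and interferon-stimulated genes (median -0.00250), and at 6 h for cholesterol genes (0.33). These follow from the change of reference; the cause of the other shifts was not tested. Without the 0 h arrays camera with the preset correlation called 26 of 108 list tests. The line test pairs arrays by time, and pairing by culture was not possible because the labels give no replicate numbers.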

Other observations

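The pattern with gene length was noticed only after long genes were seen among the largest decreases, and its tests were written after that but before any correlation with length was computed. The result of the regrouping for the response difference was fixed by its count of 0, which was already known.

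At 6 h of cisplatin, more long genes fell than rose, and more short genes rose than fell. Of 348 genes of at least 300 kb, 165 fell and 25 rose, and of 1506 genes between 100 and 300 kb, 761 fell and 92 rose, with a median change of -0.45 in each group. Of 3213 genes under 10 kb, 281 fell and 744 rose, with a median of 0.17. The rank correlation of length with the 6 h change was -0.380 in the vector line and -0.350 in the knockdown line across 12236 genes, against -0.087 and 0.005 at 1 h. Length and the line effect were nearly unrelated (-0.022).

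A greater loss of transcripts from longer genes, as when platinum lesions stop RNA polymerase, is a hypothesis that the tests leave open. The correlation was negative in both lines, at weakest -0.350, and stronger than at 1 h. Loss in proportion to length was not tested, and the median change was -0.45 both between 100 and 300 kb and from 300 kb on. Signal level does not account for the correlation, since the weakest correlation within any of 5 groups by mean signal was -0.234. The 0 h arrays do not account for it either, since 6 h against 1 h gave at weakest -0.391. The tests cannot tell blocked elongation from faster decay of the RNA of long genes, nor rule out RNA quality, which was not tested: the 3 prime to 5 prime difference was 0.14 on both 0 h arrays and 0.18 to 0.19 on the 6 h arrays for GAPDH, and 0.12 to 0.21 against 0.23 to 0.30 for beta-actin. It was highest on the knockdown 1 h array (0.24 and 0.45), whose change from 0 h was nearly unrelated to length (0.005). That is 1 array, so RNA quality stays open. Labelling of new RNA along long genes with and without cisplatin could separate blocked elongation from decay.

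When the lines were swapped at some of the times, 1 of 8 ways of grouping the arrays, the real one, gave as many genes as the 1000 of the line effect, and the highest other number was 0. For the response difference 8 of 8 gave as many as the real 0. With 8 ways the lowest possible share is 1 in 8, so this test cannot rule out chance for either count.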
